A study of Mus musculus with 6 samples.

How the data were processed

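The 6 samples were total RNA from TM3 cells, 3 without and 3 with 10 µM 4-nitrophenol (PNP) for 24 h, grouped by the dose in the labels' sample descriptions. Per the labels, RNA was amplified linearly and labelled cDNA was hybridised to Agilent mouse arrays with 1 dye. The labels name the dye Cy3, while the deposited scanner files hold red-channel columns alone, so which dye the columns stand for stays unsettled here. Each array had 62976 spots, of which 3671 were control spots and 59305 held 56605 probes.

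The deposited scanner files give intensity values. Per the file headers they were made with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name Agilent Feature Extraction 10.7. Per the file headers, the processed signal had local background and a spatial trend subtracted, was corrected for a multiplicative trend within the array, and had low values replaced by a surrogate, with no scaling between arrays. Because of the surrogate, differences of dim probes are understated. The authors' deposited normalized table holds log2 values, as found by setting each of its columns against the scanner values: each column correlated best with its own array (r from 0.9996 to 1), the sorted columns differed by at most 0.000955, as after quantile normalization, and each column's median was 8.27. Its values are uncentred and their direction is that of the scanner signal, and how it was made is not given in the sources used here. The array was designed on mouse build mm9, per the file headers, and no coordinates were used.

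Computations used R 4.3.3, limma 3.58.1 and the data.table package (1.17.8). The log2 processed signal minus each array's 75th percentile over non-control probes was the measure throughout, called the scaled log2 signal. Spots marked as non-uniform or population outliers were left out, spots of 1 probe were averaged, and a probe was tested if it was well above background on all 3 arrays of at least 1 group and kept at least 2 values per group. Of 33336 probes above background in a group, 6114 were left out for outlier spots. The scanner files carry accessions in place of gene names, so probes were named through unversioned accessions in a RefSeq list of genes of assembly GRCm38.p6, which named 33767 of 56605 probes and 23462 gene symbols; 9714 unnamed probes were tested as probes and counted in no list. This departs from the design fixed in advance, which had assumed gene names in the scanner files. Each gene was represented by its brightest tested probe over all 6 arrays, a choice blind to the groups. A gene had a value missing on 1 or 2 arrays in 2028 cases.

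Genes were tested with lmFit and eBayes of limma, PNP minus control, two-sided, with no covariates and with Benjamini-Hochberg adjustment over 13138 genes, at a threshold of 0.05. The 27222 tested probes, named or not, were also tested one by one. The 31 gene lists and the rule for named genes were fixed before the data were examined. Lists with at least 5 measured members were tested against all other genes with the camera test on z-scores, in the form that keeps genes with a missing array. It was run with a preset correlation of 0.01 and with an estimated one. The form with an estimated correlation also took its degrees of freedom from the few arrays, while the preset form took them from the genes. A call lost with it can thus be lost through either change. The fry test, on genes measured on all 6 arrays, set each list against no change. The list of endothelial markers had 4 measured members and that of mitochondrially encoded transcripts had 0, so these were not tested. Array measures were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1.

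The genes named are the 6 of smallest unadjusted p in each direction, since none passed the threshold, leaving out clone names and predicted genes, the 2 of smallest p in each list, and genes fixed in advance (among them Star, Cyp11a1, Hsd3b1, Cyp17a1, Lhcgr, Nr5a1, Esr1, Esr2, Cyp1a1, Cyp1b1, Hmox1 and Nqo1). Where a gene was not well above background on any array of a group, its fold is a bound, from the bright group's mean over the mean, per array, of the higher of its own signal and the lowest signal among probes well above background. Such a bound concerns the means and makes no allowance for the spread between arrays.

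The procedure was tested on simulated data with the real control means, missing values and fitted spread of the 13138 genes, in 20 runs with 200 changed genes each. limma called 32.8% of genes changed 1.5-fold, 85.5% of those changed 2-fold, 97.8% of those changed 3-fold and 99.3% of those changed 4-fold, and 7.15 unchanged genes per run on average. With the preset correlation, camera gave p below 0.05 in 15 of 20 runs for a list of 25 genes shifted by 0.1 and in 2 of 20 for a list with no shift. The simulated noise was independent between genes, so it holds no structure shared by arrays. The shares called also depend on the 200 changed genes per run, since the adjustment is stricter where fewer genes change. They would be lower with fewer changed genes, which was not simulated.

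Alternatives fixed in advance were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, probes above background on all 6 arrays, the mean over a gene's probes, an intensity trend with robust spread, array quality weights, a block for the replicate number of the labels, a block for slide row, the authors' normalized values, every probe tested on its own, a fold of at least 2, and leaving out each array in turn. Where an alternative changed the values or the filter or left out 1 array, the brightest probe was chosen anew, so a gene can be represented by another probe there. The scanner files used here hold no mean signal, so normexp ran on the median signal and median local background. Outlier spots kept, slide column as a block and fits within odd or even slide columns were added after seeing the data.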

Results

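Gene expression was measured in TM3 cells, a mouse cell line derived from testicular Leydig cells, the steroid-producing cells between the seminiferous tubules. Cells were kept for 24 h with 10 µM 4-nitrophenol (PNP), a nitrated phenol formed from the pesticide parathion and found in diesel exhaust, or without it. Each group held 3 samples, each hybridised to its own 1-channel Agilent array, and all 6 arrays came from 1 slide and 1 scan. The processed signals were well above background for 62.1% ± 0.240 (SD, n = 3) of the spots on control arrays and 61.6% ± 1.47 (SD, n = 3) on PNP arrays, and no spot was saturated. The number of arrays limits the precision: the median 95% interval of a gene's log2 difference was ± 0.28, or 1.21-fold either way. The sources used here do not say that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

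The comparison asked which genes TM3 cells express differently after PNP. No gene passed the test. Among the genes with the smallest p-values, Slc30a2, a zinc transporter, had a log2 difference of 1.00 (SE 0.16), with scaled log2 signals of -4.35 ± 0.18 (SD, n = 3) in controls and -3.35 ± 0.30 (SD, n = 3) with PNP. Bdp1, a subunit of the TFIIIB factor of RNA polymerase III, differed by -0.60 (SE 0.10), from -2.82 ± 0.07 (SD, n = 3) to -3.41 ± 0.11 (SD, n = 3). Their adjusted p was 0.702 for both, so these are values without a call.

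With limma, 0 of 13138 genes had an adjusted p below 0.05, and the smallest adjusted p was 0.148. At an unadjusted p below 0.05 there were 856 genes (6.52%), against 656.9 given by chance if genes were independent, 660 of them with higher and 196 with lower signal in PNP arrays. The 9 other splits of the same 6 arrays into 3 against 3 gave from 187 to 1680 such genes, the 1680 by odd against even slide columns. Of these splits 2 gave more than 856, so 856 lies within their range, and so few splits cannot test for an excess. The higher share, 77.1%, was 47.4% when arrays were scaled on their median, 61.1% after quantile normalization and 57.4% in the authors' deposited normalized values. The PNP values lay wholly above or below the control values for 1762 genes (13.4%). Chance gives 10% for genes with a value on all 6 arrays and more for the 2028 genes with a missing value. So 10% is too low a mark for all genes together. For 12866 genes (97.9%) the 95% interval excluded a change of 2-fold or more in either direction.

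On the higher side, the other genes of smallest p were Fhad1 (log2 difference 0.82, SE 0.11), Mob3b (0.74, SE 0.11), a kinase activator of the MOB family, Rimbp2 (0.76, SE 0.12), Olfr642 (0.52, SE 0.09), an olfactory receptor, and Rdh8 (0.54, SE 0.10), a retinol dehydrogenase. Fhad1 and Rimbp2 were not well above background on any control array, so their PNP signal was at least 1.62-fold and at least 1.53-fold higher, where the bound sets the PNP mean against the dimmest signal that counts as above background. Adjusted p-values of these genes ran from 0.306 for Fhad1 to 0.740 for Rdh8. On the lower side stood Ano1 (-0.98, SE 0.18), a calcium-activated chloride channel, Zfp945 (-0.57, SE 0.11), a zinc finger gene, Rpgrip1l (-0.51, SE 0.11) and Cilk1 (-0.49, SE 0.10), both with roles in the primary cilium, and Nbea (-0.49, SE 0.10). Each of the last 5 had an adjusted p of 0.740, and the Ano1 value rests on 2 PNP arrays. The 3 PNP values of each of these 12 genes lay outside the range of the controls (2 PNP values for Ano1). Since the genes were picked by smallest p in the same data, this adds no support. The same separation held for 1762 genes (13.4%).

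**Figure D1:**
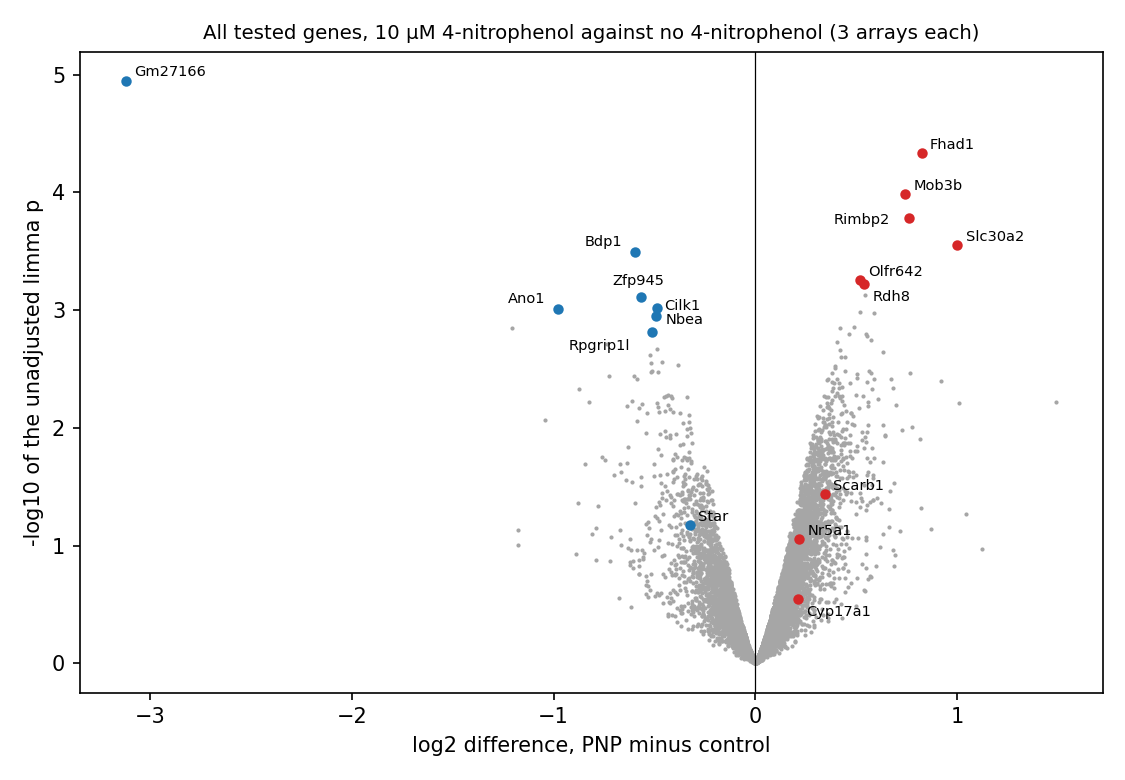
Each grey point is 1 of 13138 genes, with the log2 difference between PNP and control arrays on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Coloured points are named genes (red higher, blue lower in PNP arrays), and none of them passed an adjusted p of 0.05.

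Genes of steroid synthesis were read for whether the Leydig programme moved with PNP. Star, which brings cholesterol to the inner mitochondrial membrane, had scaled log2 signals of -3.81 ± 0.03 (SD, n = 3) in controls and -4.13 ± 0.32 (SD, n = 3) with PNP, a difference of -0.33 (95% interval -0.68 to 0.03, adjusted p = 0.791). PNP replicates 1 and 3 lay below the controls and PNP replicate 2 lay level with them. Scarb1, a receptor that takes up lipoprotein cholesterol, differed by 0.34 (95% interval 0.03 to 0.66, adjusted p = 0.740), Nr5a1, the transcription factor SF-1, by 0.22 (-0.04 to 0.48, adjusted p = 0.812), and Cyp17a1, the 17α-hydroxylase, by 0.21 (-0.21 to 0.63, adjusted p = 0.923). Cyp17a1 ran from -5.06 on PNP replicate 1 to -4.33 on PNP replicate 3, and from -5.07 to -4.78 on controls. Probes for Cyp11a1, the side-chain cleavage enzyme, and Lhcgr, the luteinizing hormone receptor, were not well above background on any array, and those for Hsd3b1 were so on at most 1 control array. Of the 18 measured members of the list of steroidogenesis and Leydig cell identity, 0 passed, also when adjusted over the list alone, and the list did not stand apart from other genes (median log2 difference 0.03, adjusted p = 0.740 with camera).

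Estrogen receptors and genes of xenobiotic response had no call, and several of their intervals were wide. The difference was 0.13 (95% interval -0.31 to 0.57) for Esr1 and 0.04 (-0.25 to 0.33) for Esr2, with adjusted p-values of 0.951 and 0.975, and 1 of the 4 Esr1 probes pointed the other way. Hmox1 and Nqo1, targets of the oxidative stress factor NRF2, differed by 0.02 (-0.62 to 0.66) and 0.22 (-0.33 to 0.77), and Sod2, a mitochondrial superoxide dismutase, by 0.18 (SE 0.10, adjusted p = 0.845). Nqo1 stood above every control on PNP replicates 1 and 3 (-0.12 and -0.02) and below every control on PNP replicate 2 (-0.99). Cyp1a1, the classic target of the aryl hydrocarbon receptor, was not well above background on any array. Cyp1b1 was above it on all 6 but had spots marked as outliers, and differed by 0.0091 (SE 0.11) when those were kept. Tiparp, another target of this receptor, differed by -0.20 (SE 0.10), and Ugt1a6b by 0.16 (SE 0.10), with its second probe of opposite sign.

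**Figure D2:**
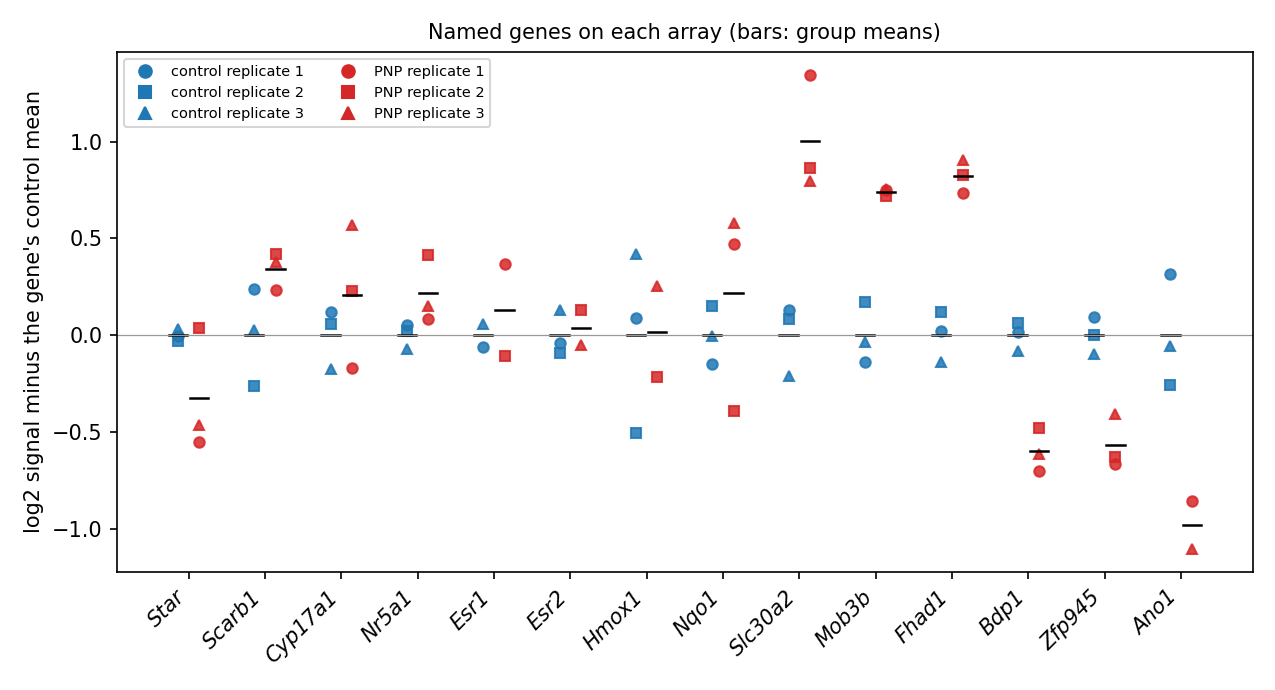
Points are single arrays (blue control, red PNP, symbols for the replicate), given as scaled log2 signal minus the gene's control mean, and bars are group means. Spots marked as outliers are not drawn, and Star of PNP replicate 2 lies with the controls while its PNP mean stands at -0.33.

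Of the 31 gene lists fixed before the data were examined, 29 had at least 5 measured members, and 3 differed from the other genes by camera with its preset correlation of 0.01. Genes of DNA replication were lower relative to the rest: 25 of 30 members had a negative difference, the median was -0.11 against 0.04 over all genes, and the adjusted p was 0.000716 (adjusted p = 0.892 with an estimated correlation). Pola1, the catalytic subunit of DNA polymerase alpha, stood at -0.37 (SE 0.16) and Orc1, of the origin recognition complex, at -0.33 (SE 0.17), where the Pola1 value rests on PNP replicates 1 and 3. Both arrays stood in even slide columns. Control replicate 2, also in an even column, had a Pola1 signal of -1.66, near their -1.68 and -1.80. The other controls had -1.26 and -1.20, so the Pola1 difference cannot be told from one of slide column. Genes of DNA repair and damage response were lower as well, with 18 of 23 members negative, a median of -0.07 and an adjusted p of 0.00116 (adjusted p = 0.892 with an estimated correlation). Within it Xrcc2, a gene of homologous recombination, stood at -0.50 (SE 0.17, PNP replicates 1 and 3 alone), while Fanca, of the Fanconi anaemia pathway, stood at 0.23 (SE 0.09) with its second probe at -0.16. For Xrcc2, control replicate 2 had -2.34, between the other controls (-2.00 and -1.79) and those PNP arrays (-2.56 and -2.53). Nuclear-encoded genes of oxidative phosphorylation were higher, with 23 of 24 positive, a median of 0.11 and an adjusted p of 0.0434 (adjusted p = 0.892 with an estimated correlation), as in Ndufa1 (0.17, SE 0.09) and Sdhd (0.19, SE 0.10), but relative to all genes their median turned to -0.0013 after quantile normalization and -0.024 in the authors' values. In each of the 3 lists, 0 members passed over all genes tested, and 0 passed when adjusted over the list alone.

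None of the 3 shifts held with an estimated correlation and the degrees of freedom of the arrays (unadjusted camera p = 0.345 for DNA replication, 0.110 for DNA repair and 0.448 for oxidative phosphorylation). The fry test, which asks whether a list moves on balance 1 way from no change, called 0 of the 29 lists. It used 24 of the 30 DNA replication members, 11 of 23 for DNA repair and 18 of 24 for oxidative phosphorylation. Its question thus differs from that of camera and rests on fewer genes. The array medians of the DNA replication list were 0.03, -0.07 and 0.01 in controls and -0.13, 0.10 and -0.28 with PNP. Without PNP replicate 1 the adjusted p of the DNA replication list was 0.152, without PNP replicate 3 it was 0.496, and with slide column (odd or even) as a block it was 0.202. For DNA repair these values were 0.340, 0.663 and 0.193, and for oxidative phosphorylation they were 0.676 without PNP replicate 1 and 0.193 with the block. Without PNP replicate 3 the oxidative phosphorylation list kept its call (adjusted p = 0.0105, and 0.996 with an estimated correlation). Without PNP replicate 2 the DNA replication list stood further off, at -0.30 relative to all genes (camera adjusted p = 9.51e-10, and 0.931 with an estimated correlation). That fit leaves only PNP arrays of even slide columns.

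**Figure D3:**
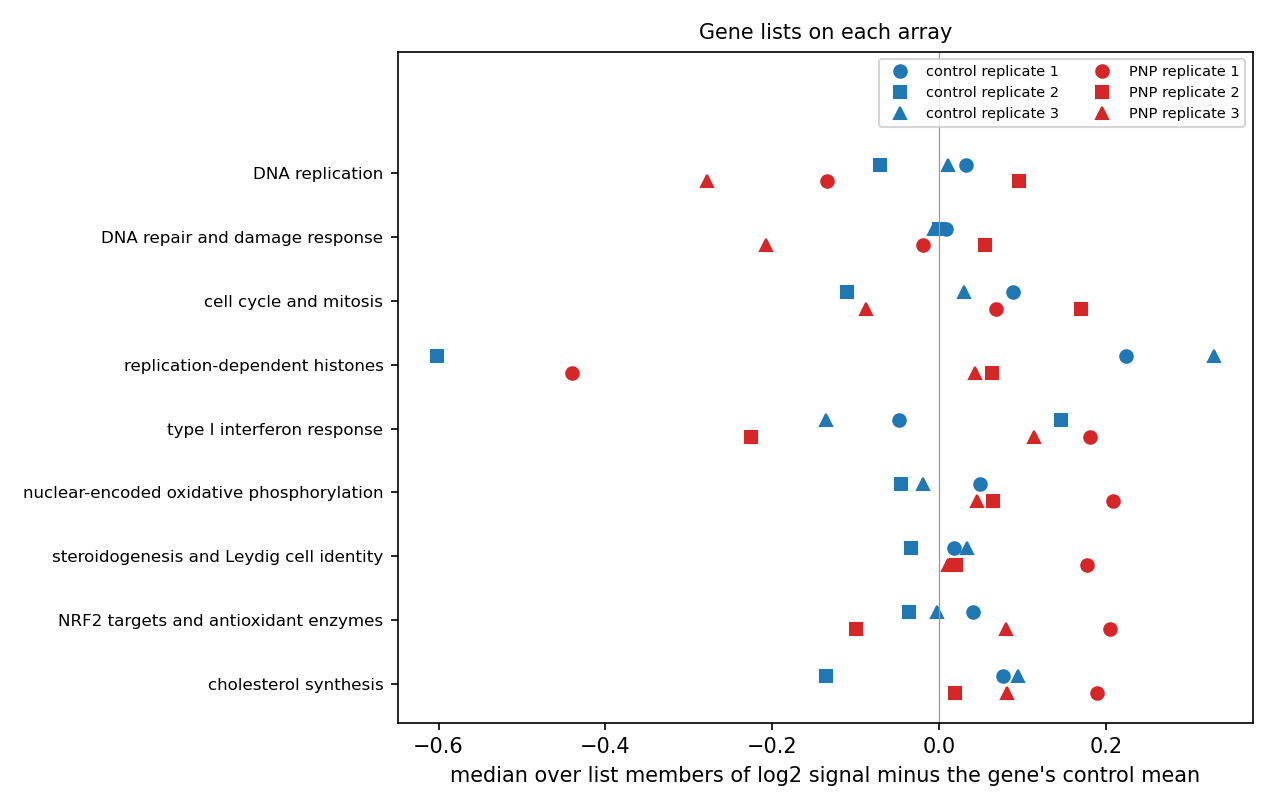
Each point is the median over the members of a gene list on 1 array, as log2 signal minus each gene's control mean (blue control, red PNP, symbols for the replicate). PNP replicate 2 lies at 0.10 for DNA replication while PNP replicates 1 and 3 lie at -0.13 and -0.28, and the oxidative phosphorylation list changes side relative to all genes under quantile normalization.

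The other 25 tested lists, beside steroidogenesis, had adjusted camera p-values from 0.194 to 0.856. Their medians ran from -0.12 for replication-dependent histones to 0.21 for germ cell markers. Cytoplasmic ribosomal proteins (median 0.10, 23 of 25 positive) and apoptosis genes (-0.013, 11 of 20 negative) shared the adjusted p of 0.194 with the histones, and circadian clock genes followed (0.12, 16 of 20 positive, adjusted p = 0.290). Ribosomal genes held Rplp2 at 0.24 (SE 0.10) and Rpl37 at -0.81 (SE 0.40), and histones held H2bc6 at 0.21 (SE 0.10) and H4c8 at 0.24 (SE 0.13), against the side of their list. Rpl37 signals ran from -3.96 to -2.11 on controls and from -4.00 to -3.46 with PNP. In the apoptosis list Apaf1, of the apoptosome, stood at 0.28 (SE 0.10) and Cflar, an inhibitor of caspase 8, at -0.30 (SE 0.14), and in the clock list Cry1, a repressor of the clock, at 0.31 (SE 0.12) and Nfil3 at 0.25 (SE 0.11).

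Stress lists did not stand apart. Heat shock proteins (median 0.03), the unfolded protein response (0.10), p53 targets (0.04), autophagy (0.04) and NRF2 targets (0.06) had adjusted p-values of 0.856, 0.448, 0.856, 0.766 and 0.680. The chaperone genes Hspa8 (0.36, SE 0.11) and Hsp90ab1 (0.09, SE 0.10) had no call, and the second tested Hspa8 probe stood at 0.10. Neither had Sdf2l1 (0.28, SE 0.12) and Creld2 (0.22, SE 0.10) of the endoplasmic reticulum, Plk2 (0.23, SE 0.10) and Eda2r (-0.19, SE 0.13) of the p53 list, Gabarapl1 (0.27, SE 0.14) and Lamp1 (0.18, SE 0.10) of autophagy, or Sod1 (0.16, SE 0.11), a superoxide dismutase. The list of aryl hydrocarbon receptor targets had a median of 0.07 and a mean of -0.0014 (adjusted p = 0.612), and phase II conjugation enzymes (-0.01, adjusted p = 0.519) held Sult2b1, a sulfotransferase, at -0.27 (SE 0.21) and Nat2, an acetyltransferase, at 0.10 (SE 0.09). PNP replicate 2 (-6.06) carried the Sult2b1 value, with -5.22 and -5.28 on the other PNP arrays and a control mean of -5.25.

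Metabolic, hormonal and mitotic lists had no call either. Cholesterol synthesis (0.08, adjusted p = 0.448) held Hsd17b7 at -0.27 (SE 0.13) and the squalene synthase Fdft1 at 0.19 (SE 0.10). Hypoxia and glycolysis (-0.0094, adjusted p = 0.448) held Car9 at -0.53 (SE 0.24, PNP replicates 1 and 3 alone) and Ndrg1 at 0.16 (SE 0.11). Those PNP arrays stood in even slide columns, with Car9 at 0.57 and 0.73, and control replicate 2, also of an even column, had 0.67. The controls of odd columns had 1.46 and 1.42, so the Car9 difference followed the column. Mitochondrial biogenesis and fatty acid oxidation (0.0011, adjusted p = 0.448) held the fatty acid binding proteins Fabp4 at -0.18 (SE 0.16) and Fabp3 at -0.19 (SE 0.22), the latter 0.09 without PNP replicate 1. Sex steroid receptors and targets (0.04, mean -0.04, adjusted p = 0.552) held Greb1, an estrogen-induced gene, at -0.52 (SE 0.27) and the membrane receptor Gper1 at -0.41 (SE 0.37). Arrays disagreed for both: Greb1 on control replicate 1 (-3.53) lay below every PNP value, and Gper1 on PNP replicate 2 (-2.72) lay above every control. Cell cycle and mitosis (0.06, mean -0.03, adjusted p = 0.755) held the mitotic kinesin Kif20a at 0.28 (SE 0.10) and the cyclin Ccnb2 at 0.25 (SE 0.10).

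Signalling lists were likewise without a call. NF-kB targets (-0.04, adjusted p = 0.448) held the cytokines Tnf at 0.28 (SE 0.13) and Ccl5 at 0.13 (SE 0.10). Type I interferon genes (0.03, mean -0.0073, adjusted p = 0.448) held Rtp4 at -0.21 (SE 0.12) and the guanylate binding protein Gbp3, without a call. Gbp3 was not well above background on any PNP array, and its control mean was at least 1.28-fold higher. Control replicate 2 (-4.55) carried most of the Gbp3 value, with -5.37 and -5.26 on the other controls and -5.58 to -5.48 with PNP. Immediate early genes (0.08, adjusted p = 0.448) held Fosb at 0.33 (SE 0.14) and Egr2 at 0.36 (SE 0.17), extracellular matrix and TGF-beta targets (-0.0021, adjusted p = 0.448) held Tgfb1 at -0.27 (SE 0.17) and Mmp3 at -0.21 (SE 0.14), and Hedgehog and Wnt signalling (0.02, adjusted p = 0.856) held Ctnnb1, the beta-catenin gene, at -0.24 (SE 0.09) and Ptch1, the Hedgehog receptor, at 0.24 (SE 0.10). Control replicate 2 (-2.52) carried most of the Tgfb1 value, with -3.12 and -3.10 on the other controls and -3.29 to -3.05 with PNP. The second probe pointed the other way for Fosb and Gabarapl1. Outlier spots also left 2 PNP values for Sdhd, Esr2, Hmox1, Hspa8, Sdf2l1, Gabarapl1 and Nfil3, 2 control values for Hsd17b7, and 2 of each for Esr1 and Eda2r.

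Markers of other testicular cell types were also read. Sertoli cell markers (9 measured, adjusted p = 0.847) included Sox9 at 0.24 (SE 0.10) and Dmrt1 at 0.24 (SE 0.11). Macrophage and leukocyte markers (10 measured, adjusted p = 0.613) included Lyz1, a lysozyme, at -0.58 (SE 0.16) and Cd3e, of the T cell receptor complex, at 0.71 (SE 0.35), or 0.24 without PNP replicate 3. Germ cell markers (9 measured, adjusted p = 0.448) included the protamine Prm2 at 0.27 (SE 0.12) and the transition protein Tnp1 at -0.67 (SE 0.36), and peritubular myoid markers (10 measured, adjusted p = 0.550) included Tpm1 at 0.19 (SE 0.10) and Myh11 at 0.19 (SE 0.15). Tnp1 ran from -5.06 to -3.43 on controls, highest on control replicate 2. Myh11 was low on control replicate 3 (-5.47), with -4.86 and -5.04 on the other controls. None of these genes passed. In all 29 tested lists 0 members passed when adjusted over the list alone, and the smallest such p was 0.0672, for Lyz1.

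The arrays differed in technical measures that went with the groups. Spots marked as outliers made up 7.75% ± 1.27 (SD, n = 3) on control arrays and 12.3% ± 0.814 (SD, n = 3) on PNP arrays, and replicate probes had a median coefficient of variation of 4.40% ± 0.205 (SD, n = 3) and 5.60% ± 0.864 (SD, n = 3). The spike-in controls had a median signal of 924 ± 26.3 (SD, n = 3) on control arrays and 794 ± 47.0 (SD, n = 3) on PNP arrays, the 75th percentile used for scaling was 12.44 ± 0.06 (SD, n = 3) and 12.27 ± 0.12 (SD, n = 3) in log2, and the local background was 70.4 ± 1.55 (SD, n = 3) and 62.4 ± 3.98 (SD, n = 3). The multiplicative trend within the array also set the groups apart, while the spatial trend of the background did not. Each of these 6 measures that set the groups apart had an exact two-sided permutation p of 0.1, the smallest that 3 arrays against 3 can give. The first principal component, 38.7% of the variance, separated odd from even slide columns and not the groups. In odd columns control replicates 1 and 3 and PNP replicate 2 stood at -7.09, -5.05 and -19.9. In even columns control replicate 2 and PNP replicates 1 and 3 stood at 3.16, 18.3 and 10.5. The second component, 23.3%, placed controls from -13.2 to -0.0948 and PNP arrays from 3.12 to 11.4. In slide row 1 stood the 3 controls and PNP replicate 1, and in row 2 the other PNP arrays. With slide row as a block limma again called 0 genes (1114 at an unadjusted p below 0.05), while camera called 5 lists, the 3 above, the histones (-0.54 relative to all genes, adjusted p = 4.73e-05) and the ribosomal proteins (0.13, adjusted p = 0.000418), with an adjusted p of 0.973 for each of the 5 with an estimated correlation. This fit rests on PNP replicate 1 alone against the controls.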

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

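The count of genes past the threshold stayed at 0 under normexp, quantile normalization, median scaling, both other filters, the mean over probes, probes on their own (1904 at an unadjusted p below 0.05 among 27222), array weights, slide row as a block, the authors' values and a fold of at least 2. It was 1 with an intensity trend and robust spread (Gm27166, adjusted p = 0.0242) and ranged from 0 to 23 when single arrays were left out, 23 of them without PNP replicate 1, 6 and 5 without control replicates 2 and 3, 2 without control replicate 1 and 1 without PNP replicate 2. Of the 23, 21 had spots bright on PNP replicates 2 and 3 alone; for the others the cause was not tested. Genes at an unadjusted p below 0.05 ran from 351 without control replicate 3 to 2079 with array weights. The replicate block gave 0 genes (594 at an unadjusted p below 0.05) and 3 lists, the same number as without it. Deviations of same-numbered samples correlated at -0.31, -0.22 and -0.03, and no control correlated best with the PNP array of its own number. So the data give no sign of pairing by number. A shared day or culture cannot be excluded this way, since same-numbered samples always stood in 1 odd and 1 even slide column.

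Among settings added after seeing the data, with slide column (odd or even) as a block 1 gene (Gm27166, adjusted p = 0.00143) and 1 list were called, and with slide column (1 to 4) as a block 0 genes and 1 list, the type I interferon response in both (-0.12 relative to all genes, adjusted p = 0.00275, and 0.939 with an estimated correlation; -0.14, adjusted p = 0.00128, with too few arrays left for an estimate). Arrays of odd columns alone gave 0 genes and 2 lists and arrays of even columns alone 125 genes and 5 lists, with the histones called in both at opposite sign (-0.28 and 0.30), fits with 1 residual degree of freedom in which the lone array of a group is assumed to vary like the other group. With outlier spots kept there were 0 genes and 3 lists, DNA replication, DNA repair and ribosomal proteins in place of oxidative phosphorylation (adjusted p = 0.908 for each with an estimated correlation).

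The 3 shifted lists became 5 with slide row as a block, 0 with an estimated correlation, 0 with fry, and 0 (without PNP replicate 1) to 4 when single arrays were left out. The oxidative phosphorylation list, relative to all genes, turned from 0.07 to -0.0013 under quantile normalization and to -0.024 in the authors' values. In odd columns the DNA replication list stood at 0.072 and the DNA repair list at 0.018 relative to all genes, against -0.19 and -0.14 in even columns. The cause of these turns was not tested. The DNA replication list was past the threshold in 17 of 22 alternatives, DNA repair in 16 and oxidative phosphorylation in 8, with adjusted p-values up to 0.496, 0.901 and 0.930, all at the preset correlation. With an estimated one, where it could be had, no list called in any alternative had an adjusted p below 0.762. That lowest value, for DNA repair without PNP replicate 2, came with an estimated correlation of 0. There the correlation did not cost the list its call, and the change to the degrees of freedom of the arrays did. Lists without a call in the report also passed in some: histones in 7 (from -0.54 to 0.30 relative to all genes over the 22), type I interferon and ribosomal proteins in 4 each, hypoxia in 3, and cholesterol synthesis, phase II enzymes, apoptosis and NF-kB targets in 1 each. Genes below background set a further limit, since only bounds can be given there.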

Other observations

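The tests of an exchange of labels, of the effect size at other spots of the genes called by slide column, of the signal trend and of PNP as the source of stray bright spots, the fits by slide column and the counts over other splits of the arrays were chosen after the results were seen.

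Of 13138 genes, 10 had an estimate of 2-fold or more, a set named after its values were seen. Higher in PNP arrays were Slco1a4, an organic anion transporter (log2 difference 1.49, SE 0.41), Il1rl2, a receptor of the interleukin 36 family (1.12, SE 0.61), Klk1b8, a kallikrein (1.04, SE 0.46), Srrm4os (1.01, SE 0.28) and Slc30a2. Lower were Col6a4 (-1.04, SE 0.29), Ccne2, the cyclin E2 that acts at the start of S phase (-1.18, SE 0.57), 4930430J02Rik (-1.18, SE 0.63), Gm4836 (-1.20, SE 0.22) and Gm27166. Only 6 of the 10 had an unadjusted p below 0.05, and none passed. Outlier spots left 2 values in each group for Gm4836, 2 control values for Col6a4 and 2 PNP values for Il1rl2. Ccne2 and 4930430J02Rik were well above background on 1 PNP array, and Slco1a4 on 1 control array. Without PNP replicate 1, Klk1b8 stood at 1.68 and passed (limma adjusted p = 0.0173). Gm27166, a predicted gene, had the smallest p of all genes: it was well above background on all 3 control arrays and on no PNP array, so its control mean was at least 2.01-fold higher (fitted log2 difference -3.12, SE 0.33, adjusted p = 0.148). Stray bright spots, described below, also occurred on all 3 controls, and whether the Gm27166 probe is one was not tested.

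The arrays of even slide columns (control replicate 2, PNP replicates 1 and 3) and odd columns (control replicates 1 and 3, PNP replicate 2) differed by more genes than the groups did. Between them 56 genes passed an adjusted p of 0.05, 38 higher in odd and 18 higher in even columns. Higher in odd columns were Car9, a carbonic anhydrase, and Slc16a3, a lactate transporter, both of the list of hypoxia and glycolysis (log2 even minus odd -0.79, SE 0.10, and -0.65, SE 0.09), the osteopontin gene Spp1 (-0.71, SE 0.11) and Stc1, a stanniocalcin (-1.54, SE 0.22). Higher in even columns were Cyp11b1 (1.06, SE 0.09), Ccn5 (0.94, SE 0.10) and Cd68 (0.65, SE 0.10). The list of replication-dependent histones had a median of -0.56, DNA replication -0.19, hypoxia and glycolysis -0.16 and type I interferon response 0.30 (camera adjusted p = 1.94e-12, 6.25e-09, 1.28e-07 and 1.58e-07, and 0.442 for each with an estimated correlation). These genes and lists are named after their values were seen.

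This split follows slide position and crosses the groups, and its cause is open. Among the 14 other probes of the called genes, 85.7% shared the sign of the called probe (exact 95% interval 57.2 to 98.2), short of the bound set in advance to exclude an effect at single spots. For the 12 called genes with other probes, the log2 difference at those other spots was 0.56 in the direction of the called probe (exact 95% interval 0.21 to 0.89, called probes 0.78), which argues against single spots as the cause for these genes as a set, while the 44 others had no other tested probe. The same split is also what an exchange of the labels of control replicate 2 and PNP replicate 2 would give, with its 56 genes against 0 for the labels as deposited, and with no independent marker of exposure an exchange and an effect of slide column cannot be told apart. The labels were kept as given, and no biological explanation was tested, since the labels name no group that follows the columns.

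The shift of the DNA replication list was weighed against a trend with signal strength and against variation between arrays that crosses the groups. With a smooth trend on mean signal removed, the DNA replication list stood at -0.15 relative to all genes, as before (interquartile range 0.12 after and 0.14 before), with an adjusted camera p of 5.89e-05 at the preset correlation, which argues against that trend as its whole cause. Before the trend was removed the call was lost with an estimated correlation (adjusted p = 0.892), which was not computed after. The oxidative phosphorylation list went from 0.07 (interquartile range 0.09) to 0.0090 (0.06) and to an adjusted p of 0.667, so the trend may account for it. Of the 9 other splits of the arrays, 3 moved the DNA replication list at least as far as the real split, so variation between arrays unrelated to PNP remains a candidate explanation, beside an effect of PNP itself, which was not tested apart from it.

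Some spots were bright on 1 or 2 arrays and dark on the others. With a gap of at least 1.5 in log2, 851 of 22380 probes searched were bright on 1 array and 88 on 2. Outside these, 6 probes were bright on 3 arrays, 2 of them on the 3 controls and 0 on the 3 PNP arrays. Of spots bright on 2 arrays, PNP replicates 2 and 3 shared 46 (11.1 times the number given by chance) and pairs of controls 35 (17.3 times). PNP replicate 1 shared 0 with the other PNP arrays. PNP as the source would need PNP replicate 1 to show the spots that the other PNP arrays shared. Of 50 spots bright on PNP replicates 2 and 3 and dark on controls, 0% were well above background on PNP replicate 1 (exact upper bound 7.11%). The bound takes spots as independent and rests on 1 array, so it is too tight for spots that lie close together. The 46 shared spots lay close together, with a median of 2.53 spot positions to the nearest other, against 18.1 for random probes (lowest 5% of 1000 draws 14.5), so a disturbance of the array surface at like places on neighbouring arrays may have lit them. A spatial trend of the background, as the scanner software gives it, was largest on PNP replicates 2 (21.5) and 3 (15.2) and at most 5.27 on the other arrays.

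Other splits of the 6 arrays into 3 against 3, 10 in all with the real one, are too few for a share under 0.05. For genes past the threshold the real split gave 0, a count that any split reaches, and the highest other gave 56, which points to a structure of the arrays or samples whose cause is open. For shifted lists the real split gave 3, 7 of the 10 splits gave at least as many and the highest other gave 8. In both cases the highest other was the split by odd and even slide columns, and with that column as a block the real comparison gave 1 gene and 1 list.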
